A study of Arabidopsis thaliana with 72 samples.

How the data were processed

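Total RNA of whole leaf, mesophyll and vasculature of Arabidopsis Col-0 seedlings was purified with RNeasy columns and labelled with the WT Terminal Labeling kit, per the labels' protocols. The isolated tissues were freed with enzymes and sonication, per the labels' protocols. The deposited values are intensities on a linear scale, which the authors made with GCRMA, per the submitters' processing notes; its version and the annotation behind it are not given in the sources used here. GCRMA corrects background with probe sequence, normalizes arrays to a common distribution and sums probes into probe sets, so differences shared by most genes of a group would be removed by it. The deposited intensities ran from 0.835 to 18000, and array medians from 3.29 to 3.77. All 72 value columns matched the title of 1 sample each.

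Day length, tissue, Zeitgeber time and seedling age were taken from the labels, which gave 6 groups of 12 arrays, with 1 array for each of 6 times on each of 2 days. No pair of arrays was near identical, so none was treated as a repeat. Samples share replicate numbers between groups through their time points, and the check of whether these pair the samples stands with the settings tried. No scan date or slide was used here.

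Values were analysed as log2(intensity + 1). A probe set was kept when its intensity was above 2.77, the 40th percentile of all values, in at least 6 arrays, which left 21827 of 28583. Fold changes are on this scale, so those of dim genes are understated by the added 1 and depend on the background correction. Probe sets were named from the platform table through Entrez identifiers and the RefSeq table of assembly TAIR10.1. Of the probe sets, 16722 had 1 gene by the platform annotation, 759 had several and 11102 were not listed there; 16574 of the 16722 were found in RefSeq. Among the kept probe sets 12140 had 1 gene, 631 several and 9056 none listed, and they named 12016 genes, of which 154 had more than 1 probe set. Probe sets of 1 gene were kept apart, and no gene was named from a probe set with several.

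Group means were compared with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), with lmFit and eBayes and a term for each group at each time, using the arrays of the compared groups alone. The contrast averaged the 6 times. A call needed a Benjamini-Hochberg adjusted p under 0.05 over all kept probe sets and a difference of at least 1. The interaction used the 48 arrays of mesophyll and vasculature. The day length difference at each time used 1 contrast per time, adjusted over the probe sets of that contrast. Cycling was tested with limma's moderated F test of a 24-hour cosine and sine within each group, with an adjusted p under 0.03; the series design names HAYSTACK at that threshold, which was not used here. A rhythm difference was the moderated F test of the group by cosine and sine interaction at an adjusted p under 0.05, and its vector difference is the distance between the 2 fitted cosine and sine pairs. All tests were two-sided. Overlaps are given with the number that independent lists would share. Figures were drawn with matplotlib 3.10.9.

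Gene lists were tested with camera at its preset correlation and with an estimated one, adjusted over the lists, and with fry. Lists of mesophyll and photosynthesis markers, phloem, photoperiodic flowering, circadian clock, chlorophyll synthesis, cold response, starch metabolism, stomatal lineage, plastid-encoded genes, early wound and defence, flavonoid synthesis and glucosinolate synthesis were fixed before the data were examined, as were the tests, the rule for named genes and most of the alternatives. Many of their members had no probe set of 1 gene, so further lists were chosen after the probe names were seen and before group differences were computed, and a gene can stand in a list of each kind. The fixed lists of dark and sugar starvation, epidermis, heat shock, jasmonate response, mitochondrion-encoded genes, photoreceptors, salicylate, and xylem and procambium had 0 kept probe sets and gave no result. Counts adjusted over the list alone equalled the counts of members past the call for every fixed list and mean comparison.

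Genes are named by a rule. For vasculature against mesophyll they are the 8 highest and 8 lowest by the smaller of the 2 day lengths' differences, past the call in both with the same sign at all 12 time points; against whole leaf, the 4 highest and 4 lowest by the same rule. For day length they are the 6 highest and 6 lowest per tissue with the same sign at 5 or more of 6 times. For cycling they are the 5 largest amplitudes per group, and for rhythm differences the 6 largest vector differences per comparison. Members of the clock and flowering lists, up to 4 members per other list past the call, and members not past it as values, complete the rule.

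The tests were tried on simulated data with known answers. With 200 changed probe sets of 21827, the mean comparisons and the interaction recovered 99% to 100% and called no unchanged probe set. The cosine test recovered 42% to 86% of amplitudes of 0.5 and 88% to 100% of amplitudes of 1, with 2.11% to 3.77% of calls unchanged. The rhythm difference was less well held. In 1 run 6.15% to 11% of its calls were unchanged probe sets, above a limit of 10% set for that check in the comparison of short day vasculature with mesophyll. Over 10 runs the share was 5.92% to 8.86% when each group kept its own spread and 4.81% to 5.43% when both groups had the same, so the excess came with unequal spreads. A fit with a separate spread for each group, added after this was seen, gave 6.92% to 9.18% and did not remove it. For a shifted list of 15 genes camera gave p = 3.1e-101, and 0 of 20 unshifted lists had p under 0.05. The simulated probe sets varied independently and no other gene was shifted. This check therefore cannot show how camera at its preset correlation does with correlated genes.

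The alternatives tried were no filter and a stricter filter (above the 60th percentile in 12 arrays), no minimum difference, no offset, quantile normalization, centring on array medians, a trended robust prior, array weights, all 72 arrays in 1 fit, each day alone, a block for the time point, other tests of rhythm, the day as a covariate, only cycling genes for the rhythm difference, and each array left out in turn. Each set of 100 splits held the real one and 99 drawn with a fixed seed; the swaps of days were all 32.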

Results

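Transcript levels were measured in cotyledons of Arabidopsis thaliana seedlings of the Columbia accession (Col-0) on 72 Gene 1.0 ST arrays made for Arabidopsis by Affymetrix. Seedlings were grown in long days (16 h light and 8 h dark) or short days (8 h light and 16 h dark). RNA came from the whole cotyledon (called whole leaf in the labels), from its isolated mesophyll, the photosynthetic ground tissue, or from its isolated vasculature. Each of the 6 combinations of day length and tissue has 12 arrays, taken every 4 h at Zeitgeber times (ZT, hours after lights on) 0 to 20 on day 9 and again on day 10. Array medians of the deposited intensities lay between 3.29 and 3.77, and the number of arrays, 2 for each time and group, limits the precision. No label says that the 2 arrays of a time came from separately grown cultures, so p-values measure only the spread between these samples, which may be technical. Of 28583 probe sets, 21827 passed the filter on low values. The first principal component held 50.2% of the variance and the second 21.3%. Long day whole leaf replicate 7 stood apart, with a mean intensity of 54.2 against at least 67.8 in every other array and a correlation of 0.9686 with the array of the same time on the other day.

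The comparison of vasculature with mesophyll asked which genes had higher levels in the isolated veins than in the isolated mesophyll. In long days BGLU33, a member of the beta-glucosidase family, was 9.24 ± 0.08 higher in vasculature on the log2 scale (SE, n = 12 arrays per group; 603-fold; limma adjusted p = 1.3e-21). In short days its difference was 9.06 ± 0.16 (532-fold; limma adjusted p = 9.8e-17). The other 7 genes with the largest positive differences had the loci AT1G68230 (8.49 in long days and 8.45 in short days), AT3G01940 (7.94 and 8.18), AT2G27140 (8.11 and 7.65), AT3G61210 (7.42 and 7.41), AT1G29520 (7.96 and 7.39), AT2G32880 (8.96 and 7.29) and AT5G18600 (7.93 and 7.22). At the other end, ABR1, a transcription factor of the AP2/ERF family, fell by 7.21 ± 0.07 in long days and by 7.65 ± 0.16 in short days in vasculature against mesophyll (148-fold and 201-fold; limma adjusted p = 4.9e-21 and 4.8e-16). CSLC04, a glucan synthase of xyloglucan formation, differed by -7.22 ± 0.17 and -7.04 ± 0.14, and pEARLI4 by -6.93 ± 0.21 and -6.99 ± 0.09. The remaining 5 were AT5G13200 (-7.36 and -7.31), AT3G02840 (-7.22 and -7.1), AT5G52050 (-7.47 and -7), AT4G38550 (-7.19 and -6.96) and AT1G61890 (-7.2 and -6.91). By the rule that chose them, each of these 16 genes kept its sign at all 6 times in both day lengths. Their lower group lay near 2 to 3 on the log2 scale, except for AT2G32880 in short days, and so near the bottom of the measured range; folds of this size depend on the background.

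Most of the measured photosynthesis markers were lower in vasculature. Of 9 measured members of the list of mesophyll and photosynthesis markers, 7 were lower and none higher in each day length, and 7 were also lower when adjusted over the list alone. SBPASE, a Calvin cycle phosphatase, fell by 2.94 ± 0.16 in long days and by 2.83 ± 0.08 in short days. PRK, another Calvin cycle enzyme, had -2.54 and -2.3, ATPC1 of the plastid ATP synthase -2.34 and -2.21, and the light-harvesting protein LHCB4.1 -1.66 and -1.89. The list's camera test gave adjusted p = 0.00023 in long days and 2.2e-05 in short days, and adjusted p = 0.37 and 0.14 with an estimated correlation. In the wider list of nuclear-encoded photosynthesis genes, which was chosen after the probe names were seen, 11 of 17 members were lower in each day length (medians -1.33 and -1.19). Its camera adjusted p was 1.6e-05 and 2e-06, against adjusted p = 0.28 and 0.14 with an estimated correlation. All 4 photorespiration genes were lower, among them GLYK, glycerate kinase (-3.88 and -3.84), HPR, hydroxypyruvate reductase (-2 and -1.88), and GLDT (-1.36 and -1.07), with camera adjusted p = 0.0092 and 0.0042, and adjusted p = 0.28 and 0.14 with an estimated correlation. Of 3 starch metabolism genes 2 were lower, PWD, which phosphorylates glucans (-1.58 and -1.36), and SBE2.2, a branching enzyme (-2.7 and -2.24). The starch list had adjusted p = 0.034 and 0.051, and adjusted p = 0.17 and 0.21 with an estimated correlation. Of 3 chlorophyll synthesis genes, GSA1 (-1.7 and -1.79) and CHLM (-1.35 and -1.12) were lower and PORB differed by 0.36 and -0.03. Of 63 plastid-encoded genes 3 were lower in long days and 7 in short days, with ndhF at -1.62 and -2.01 and psbM at -1.47 and -1.73. The plastid list's median was -0.2 and -0.37, with camera adjusted p = 3e-04 and 3.6e-07 and adjusted p = 0.53 and 0.37 with an estimated correlation.

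Some genes of vein function were higher in vasculature. SWEET11, a sucrose exporter of phloem loading, was 2.39 ± 0.12 higher in long days and 2.93 ± 0.2 in short days. OPS, a gene of protophloem formation and the other measured phloem marker, was higher in short days alone by the call, by 1.11. The list of vascular signalling and transport, chosen after the probe names were seen, had 7 of 14 members higher and 1 lower in long days, and 9 higher and 1 lower in short days (medians 1.12 and 1.49). Its higher members included GTR2, a glucosinolate transporter (6.66 and 5.94), the peptide genes CLE26 (6.27 and 5.66) and CLE41 (3.04 and 3.48), and LHW, a factor of vascular cell divisions (3.43 and 3.62). The lower member was GTR1, the other glucosinolate transporter (-2.56 and -2.27). Its camera adjusted p was 0.0092 and 0.0079, against adjusted p = 0.17 and 0.21 with an estimated correlation. Of 11 SWEET sugar transporters 4 were higher and 1 lower in each day length, with SWEET4 at 5.29 and 5.8, SWEET1 at 3.45 and 3.03, and SWEET2 at -3 and -2.8. Of 10 iron deficiency genes 4 were higher and 1 lower in long days, and 2 higher and 1 lower in short days. The iron peptide genes IMA2 (5.16 and 5.02) and IMA1 (3.49 and 2.95) were higher and PYE, a regulator of iron balance, lower (-2.26 and -1.95). Cytosolic ribosomal protein genes were higher for 44 of 113 members in long days and 25 in short days, with none lower (medians 0.79 and 0.58). This list had camera adjusted p = 1.1e-10 and 3.6e-07, and adjusted p = 0.28 and 0.41 with an estimated correlation. Of 8 cell cycle genes 3 and 5 were higher, including TOPII (2.05 and 2.71), AUR1 (1.54 and 2.18) and BUBR1 (1.07 and 1.53). The cell cycle list had adjusted p = 0.051 and 0.012, and in short days adjusted p = 0.21 with an estimated correlation. Of 9 secondary wall genes 3 were higher in each day length, GUT2 (3.16 and 2.39), TBL33 (1.36 and 1.13) and HCT (1.25 and 1.22).

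Wound and early stress genes were lower in vasculature than in mesophyll for 13 of 15 members in each day length, with 1 member higher (medians -3.78 and -3.43). For this list mesophyll also lay above whole leaf (medians 2.84 and 4.26), so these values need not show levels of the intact tissues. AR781 (-6.69 and -6.37), the calmodulin-like genes CML38 (-6.64 and -6.08) and CML37 (-4.85 and -5.26), and the ubiquitin ligase gene PUB23 (-5.94 and -6.76) had the lowest values. The list's camera adjusted p was 1.6e-05 and 6.3e-06, and adjusted p = 0.17 and 0.14 with an estimated correlation. STZ, a stress-induced zinc finger gene and the measured member of the early wound list fixed before the data, differed by -4.05 and -2.88. Of 7 cold response genes 5 were lower in each day length, with COR47, a dehydrin, at -4.81 and -2.93, COR15A at -2.93 and -2.34, KIN2 at -2.41 and -1.59 and COR15B at -1.4 and -1.62. The cold list had adjusted p = 0.0092 and 0.019, and adjusted p = 0.17 and 0.21 with an estimated correlation. BZIP60, a factor of the unfolded protein response, fell by 3.58 and 4.01. Of its list of 12, 2 members were higher and 2 lower in long days and 1 each way in short days. Like the wound list, STZ, COR47 and BZIP60 lay above whole leaf in mesophyll, as given below.

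Among flowering and clock genes, CDF5, a DOF factor that represses CONSTANS, was named by 2 probe sets, both higher in vasculature. The first differed by 2.81 and 2.52 and the second by 1.3 and 1.35. SNZ, an AP2-like flowering repressor, fell by 1.12 in long days. The clock gene RVE6 had -1.24 in long days, past the call, and GI, a clock and photoperiod gene, had 0.77 ± 0.12, under the minimum difference of 1. The photoperiodic flowering list gave 2 of 4 probe sets higher and 1 lower in long days, 2 higher in short days, and adjusted p = 0.38 and 0.11. Of 12 clock-associated genes 2 were lower in each day length. The remaining lists held few calls: 4 of 11 heat genes lower in short days and 3 in long days (HSP17.8 -2.36 in long days), 3 higher and 1 lower of 8 glucosinolate and myrosinase genes in long days and 3 and 2 in short days, 1 of 7 jasmonate pathway genes lower in each (OPCL1 -2.16 and -1.18), 2 of 42 reproductive genes higher in each, and 2 of 9 starch and plastid sugar genes lower in each. Of 16 sugar starvation genes 2 were higher and 2 lower in long days and 1 was higher in short days. The single glucosinolate synthesis gene was higher in long days, 1 of 3 cuticle genes was lower in long days, 1 of 6 guard cell genes was lower in short days, and 1 of 5 auxin and shade genes was higher in short days. None of the 3 stomatal lineage, 2 flavonoid or 11 anthocyanin decoration probe sets passed in either day length.

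In total, 5570 probe sets differed between vasculature and mesophyll in long days (2781 higher and 2789 lower in vasculature) and 5474 in short days (2714 higher and 2760 lower), by limma with a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 1. The 2 day lengths shared 4764 of these, all in the same direction, where independent lists would share 1400. They used separate arrays. Centring each array on its median shifted the median of all probe sets by -0.17 in long days and -0.18 in short days, and the list medians given with a direction here are all farther from 0 than that. With no minimum difference the counts were 15985 and 16031, by the construction of that setting.

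The comparisons with the whole leaf asked how each isolated tissue differed from the organ it came from; both use the same whole-leaf arrays, so their values are not independent. In mesophyll STZ was 8.44 ± 0.1 higher in long days (348-fold; SE, n = 12 arrays per group; limma adjusted p = 1.5e-19) and 9.09 ± 0.1 higher in short days (546-fold; limma adjusted p = 4e-19). AT4G29780 (8.37 and 8.31), AT1G15010 (7.85 and 8.31) and AT2G34930 (7.51 and 7.95) followed. PYK10, a beta-glucosidase of endoplasmic reticulum bodies, fell by 5.8 ± 0.27 and 6.02 ± 0.28 (55.7-fold and 65.1-fold), beside AT5G44020 (-7.25 and -5.78), AT4G23680 (-5.96 and -5.74) and AT3G16370 (-5.7 and -5.67). Of the 15 wound and early stress genes 12 were higher in long days and 14 in short days, none lower (medians 2.84 and 4.26). AR781 had 7.27 and 7.3, CML38 6.79 and 7.44, ORA47, a jasmonate-related factor, 7.36 in long days, and PUB23 7.23 in short days. This was the camera call that held with an estimated correlation (adjusted p = 2.7e-12 and 2.9e-12, and adjusted p = 0.0022 and 0.048 with an estimated correlation). BZIP60 (4.62 and 5.27), OPCL1 of jasmonate synthesis (4.56 and 5.58), COR47 (2.67 and 3.13) and HSP17.8 (2.48 and 2.25) were also higher in mesophyll. The heat list had 4 of 11 members higher in long days, with adjusted p = 0.034, and adjusted p = 0.31 with an estimated correlation. Guard cell genes FMA (-2.24 and -1.97) and BLUS1 (-1.88 and -1.37), the endoplasmic reticulum body gene NAI2 (-4.56 and -5.47), GTR2 (-3.78 and -2.3) and SWEET11 (-1.6 and -1.65) were lower. None of the 9 photosynthesis markers passed in either day length, with medians of 0.12 and -0.07; after quantile normalization the long day median was -0.01.

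**Figure D1:**
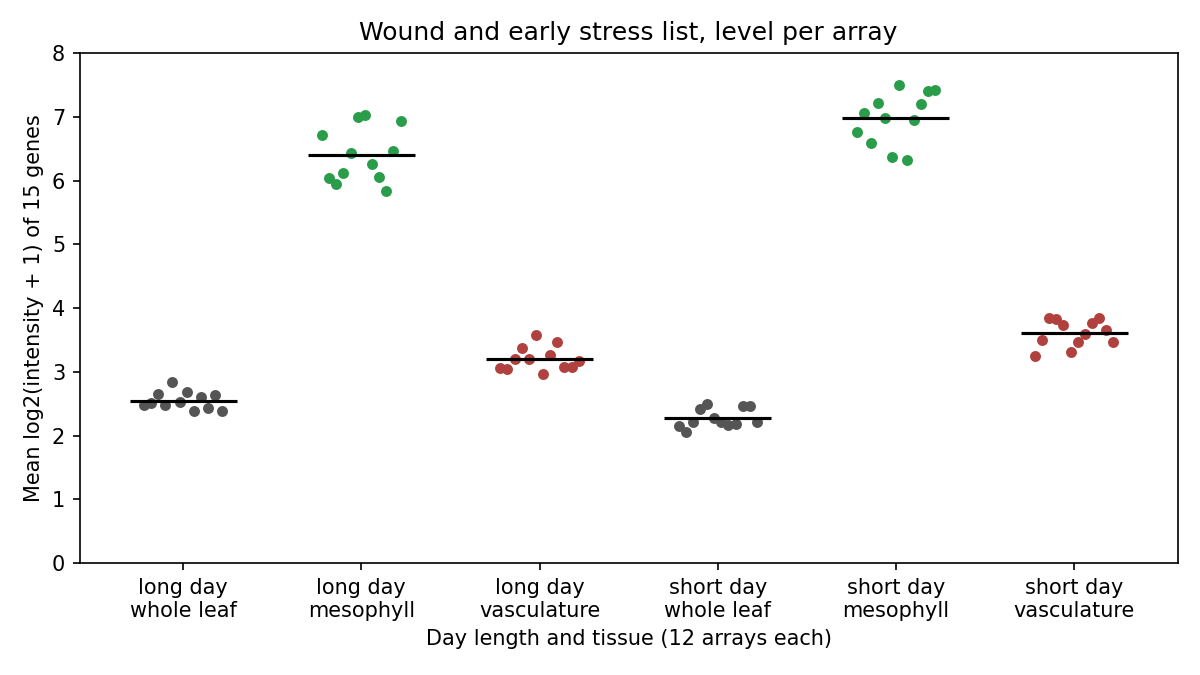
Mean log2(intensity + 1) of the 15 measured wound and early stress genes (vertical axis) in each of the 12 arrays (points) of the 6 groups of day length and tissue (horizontal axis), with the group mean as a line. The lowest mesophyll array lay at 5.83, and the highest array of the other 4 groups at 3.85.

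In vasculature against the whole leaf, AT1G29520 (7.45 and 6.55), AT3G01940 (6.48 and 6.71), AT1G08160 (6.96 and 6.31) and AT3G01950 (6.07 and 6.14) were highest. AT5G44020 (-7 and -8.11), AT5G65380 (-6.24 and -6.49), AT2G45180 (-6.19 and -5.99) and AT1G21060 (-5.81 and -6.76) were lowest. Of the 9 photosynthesis markers 8 were lower in each day length, with adjusted p = 0.0021 and 1.4e-05, and adjusted p = 0.38 and 0.052 with an estimated correlation. Vascular signalling genes were higher for 6 of 14 members in long days and 8 in short days, with 1 lower in short days (adjusted p = 0.0076 and 5e-04, and adjusted p = 0.25 and 0.052 with an estimated correlation). Ribosomal protein genes were higher for 23 and 13 of 113, with 1 lower in short days (adjusted p = 9.4e-12 and 4.8e-07, and adjusted p = 0.25 and 0.24 with an estimated correlation). Guard cell genes were lower for 3 and 4 of 6 (adjusted p = 0.013 and 0.0038, and adjusted p = 0.25 and 0.1 with an estimated correlation). Wound genes were higher for 4 of 15 members with 1 lower in long days, and higher for 6 in short days (short day adjusted p = 0.0034, and adjusted p = 0.052 with an estimated correlation). Mesophyll against whole leaf gave 2452 probe sets in long days (1260 higher, 1192 lower) and 2658 in short days (1362 higher, 1296 lower). Vasculature against whole leaf gave 4391 (1991 higher, 2400 lower) and 4570 (2094 higher, 2476 lower).

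Day length changed fewer genes on average over the day. In whole leaf PPDK, pyruvate orthophosphate dikinase, was 2.72 ± 0.14 higher in long days (6.57-fold; SE, n = 12 arrays per group; limma adjusted p = 1.9e-09; higher at 6 of 6 times), and in mesophyll 2.02 ± 0.21 higher (limma adjusted p = 1.8e-05). COR27, a cold- and light-regulated gene linked to the clock, fell by 2.29 ± 0.15 in whole leaf (limma adjusted p = 1.8e-08), by 2.3 ± 0.19 in mesophyll and by 2.01 ± 0.12 in vasculature. The other highest genes of whole leaf were AT1G66100 (3.63 ± 0.42), AT5G42530 (3.51 ± 0.5), AT1G55265 (2.45), AT3G04210 (2.42) and AT1G35350 (2.35). The lowest were AT4G28780 (-2.53), ZW9 (-2.5 ± 0.19), AT5G45670 (-2.18), AT5G48900 (-2.18) and AT3G05640 (-2.16). In mesophyll AT3G54830 (1.94), AT1G55265 (1.9), AT5G06890 (1.89), AT5G21940 (1.51) and AT5G64401 (1.49) were higher. The ubiquitin ligase gene PUB22 (-2.67 ± 0.47; limma adjusted p = 0.00096), AT1G59865 (-2.37), AT1G67870 (-2.17), AT2G31945 (-2.13) and AT2G24600 (-1.97) were lower. In vasculature AT3G46880 (3.19 ± 0.2), AT1G63530 (2.64), AT3G24230 (2.63), AT1G07300 (2.49), AT5G54130 (2.18) and AT1G07590 (2.01) were higher, and AT1G62510 (-2.29), AT4G29780 (-2.21), COR47 (-1.79 ± 0.08), NAI2 (-1.66 ± 0.24) and AT1G21830 (-1.66) lower. PIF7, a phytochrome-interacting factor, was 1.45 ± 0.09 higher in long day vasculature (limma adjusted p = 5.1e-08).

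Cold response genes were lower in long days for 4 of 7 members in vasculature, 2 in whole leaf and 1 in mesophyll. COR15A fell by 1.3 in vasculature and by 1.16 in whole leaf, and KIN2 by 1.1 in vasculature. The list's camera adjusted p was 0.00077 in vasculature and 0.028 in whole leaf, against adjusted p = 0.086 and 0.58 with an estimated correlation. Ribosomal protein genes had medians of -0.32 in whole leaf, -0.36 in mesophyll and -0.16 in vasculature, with 2, 2 and 1 of 113 members past the call. Their camera adjusted p was 3.9e-17, 2.5e-18 and 6e-06, and adjusted p = 0.33, 0.53 and 0.54 with an estimated correlation. In mesophyll 4 of 15 wound genes were lower in long days, among them PUB23 (-1.14), PUB24 (-1.02) and PP2C (-1.51), with adjusted p = 0.01, and adjusted p = 0.53 with an estimated correlation. In vasculature 3 were lower, STZ (-1.2), ORA47 (-1.36) and WRKY29 (-1.47), with adjusted p = 0.047, and adjusted p = 0.54 with an estimated correlation. In whole leaf WRKY6 was higher (1.11), and 13 of the 15 members had values above 0 (median 0.12), against 2 in mesophyll (median -0.38) and 5 in vasculature (median -0.16). The whole leaf list had adjusted p = 0.016, and adjusted p = 0.33 with an estimated correlation. In isolated mesophyll the list mean was 6.4 in long and 6.98 in short days, against 2.55 and 2.28 in whole leaf. For these genes a difference between the isolations of the 2 day lengths cannot be told apart from day length in the isolated tissues. Of the plastid-encoded genes psbT (-1.04) and rpl32 (-1.18) were lower in long day whole leaf, with adjusted p = 0.00021 for the list, and adjusted p = 0.74 with an estimated correlation. Further members past the call were PYK10 (-1.58 in whole leaf and -1.35 in mesophyll), STOMAGEN (-1.36 in whole leaf), IAA29 (-1.05 in whole leaf), HAT2 (1.06 in mesophyll) and COV1 (-1.11 in mesophyll). None of the photosynthesis, phloem, starch, chlorophyll or photoperiodic flowering probe sets of the lists fixed before the data passed in any of the 3 tissues, and the counts adjusted over each list alone were also 0.

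Averaged over the day, 407 probe sets differed between long and short days in whole leaf (213 higher, 194 lower in long days), 266 in mesophyll (84 higher, 182 lower) and 322 in vasculature (163 higher, 159 lower). Whole leaf and mesophyll shared 80 (75 in the same direction; 4.96 if independent), whole leaf and vasculature 48 (44; 6) and mesophyll and vasculature 24 (24; 3.92). These comparisons share no arrays. With the arrays of day 9 alone the counts were 194, 78 and 181, and with those of day 10 alone 191 in whole leaf and 162 in mesophyll, with fewer arrays in each fit.

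More probe sets differed at ZT8, ZT12 and ZT16 than in the comparison averaged over the day in all 3 tissues, and in whole leaf at each of the 6 times. At ZT16, when long-day seedlings reached the end of their light period and short-day seedlings had been dark for 8 h, 1909 probe sets differed in whole leaf, 1440 in mesophyll and 1326 in vasculature. At ZT12 the counts were 1391, 1328 and 991, and at ZT8 1051, 645 and 500. At ZT0, ZT4 and ZT20 they were 787, 634 and 588 in whole leaf, 180, 223 and 141 in mesophyll, and 376, 292 and 294 in vasculature. At any of the 6 times 3610, 2721 and 2285 probe sets differed. The whole leaf count at ZT0 was 510 without long day whole leaf replicate 7, and the mesophyll counts at ZT0, ZT4 and ZT20 were 398, 504 and 384 when all 72 arrays shared 1 estimate of the spread.

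**Figure D2:**
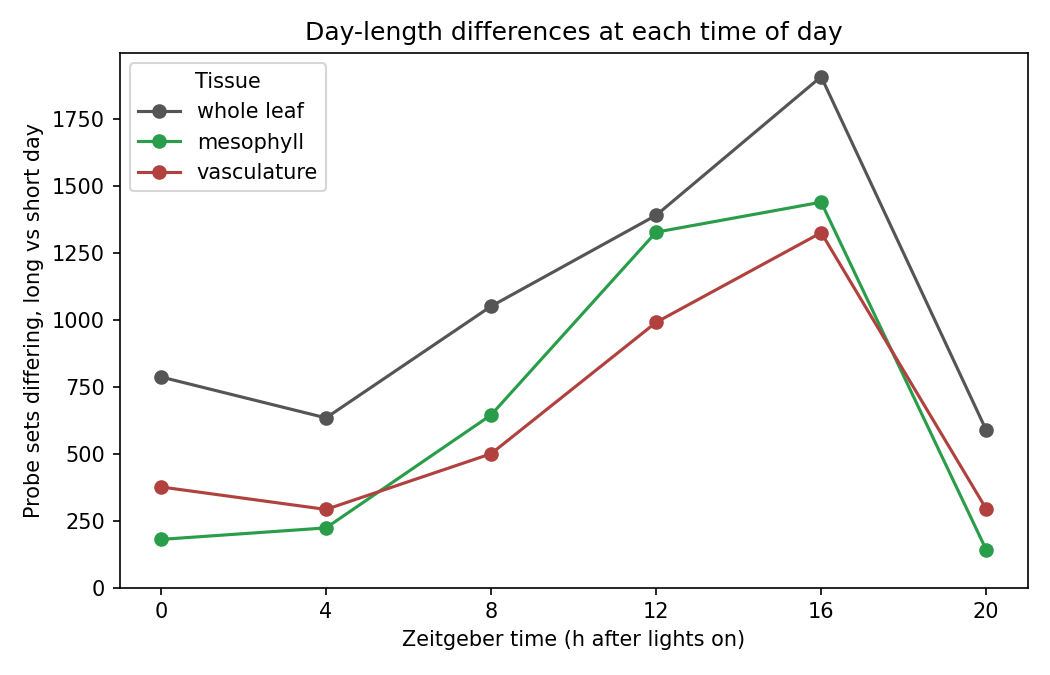
Number of probe sets differing between long and short days (vertical axis; limma adjusted p under 0.05 and a log2 difference of at least 1) at each Zeitgeber time in hours (horizontal axis), 1 line per tissue. The counts were highest at ZT16 in all 3 tissues, with 1909 in whole leaf, 1440 in mesophyll and 1326 in vasculature.

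The interaction tested whether the difference between vasculature and mesophyll itself differed between day lengths. PIF7 (1.55; adjusted p = 0.00019) and PUB22 (2.51; adjusted p = 0.00062) had a larger value for vasculature minus mesophyll in long days. PPDK (-2.05; adjusted p = 1.4e-06), COR47 (-1.88; adjusted p = 2.4e-11), ORA47 (-1.89; adjusted p = 0.00025), HAT2 (-1.4; adjusted p = 0.00044), STZ (-1.17; adjusted p = 0.00012) and SNZ (-1.1; adjusted p = 0.00013) had a smaller one. Single arrays of PPDK in vasculature lay between 2.04 and 3.46 on the log2 scale over both day lengths. Those of PIF7 in short day vasculature lay between 1.67 and 2.64. Both are near the bottom of the measured range, where low signal can hide a change, so these 2 interactions may depend on the background. Of the 15 wound genes 3 went each way, of 113 ribosomal protein genes 1 was positive, and of 7 cold genes COR47 was the member past the call. For the wound genes a difference between the isolations of the 2 day lengths cannot be told apart from day length here either. In total 497 probe sets passed, 302 positive and 195 negative.

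Rhythms were described by a 24-hour cosine in each group, after the series design, which names a search for cycling genes in each tissue. GI had among the largest rhythms in 5 groups, with amplitudes of 3.42 ± 0.37 in long day whole leaf (SE, n = 12 arrays), 3.21 ± 0.34 in long day vasculature, 3.64 ± 0.65 in short day whole leaf, 3.39 ± 0.61 in short day mesophyll and 3.67 ± 0.51 in short day vasculature. Its fitted peaks were at 8.37, 7.1, 6.57, 6.46 and 5.67 h. In long day mesophyll GI had an amplitude of 3.18 ± 0.62 and a peak at 6.9 h. The difference in GI's rhythm did not pass in any pair of groups compared (limma adjusted p = 0.37 to 0.99). AT4G15430 had amplitudes of 3.95 ± 0.22 and 3.88 in whole leaf and 3.5 and 3.59 in mesophyll, peaking between 21.9 and 23.5 h. AT1G55960 reached 3.98 ± 0.42 and 4.01 in mesophyll, with peaks at 2.17 and 0.873 h. Further genes of large amplitude in long days were THI2.2, a thionin (3.47 ± 0.55, peak 6.14 h), AT1G56300 (3.26) and AT1G73480 (3.23) in whole leaf, and AT4G36850 (3.25), AT4G16146 (3.23) and AT3G62550 (3.19) in mesophyll. In long day vasculature CCL (3.04), AT2G47870 (2.88), the iron peptide gene IMA2 (2.75 ± 0.35, peak 18.6 h) and AT4G36850 (2.39) followed. In short days they were AT4G30650 (3.46), AT1G56300 (3.41) and AT2G15020 (3.36) in whole leaf and AT5G48490 (3.34) and AT5G35970 (3.22) in mesophyll. In short day vasculature AT2G47870 (3.71), COR15A (3.39, peak 8.52 h), COR27 (3 ± 0.36, peak 12.2 h) and AT2G41250 (2.73) stood beside GI.

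**Figure D3:**
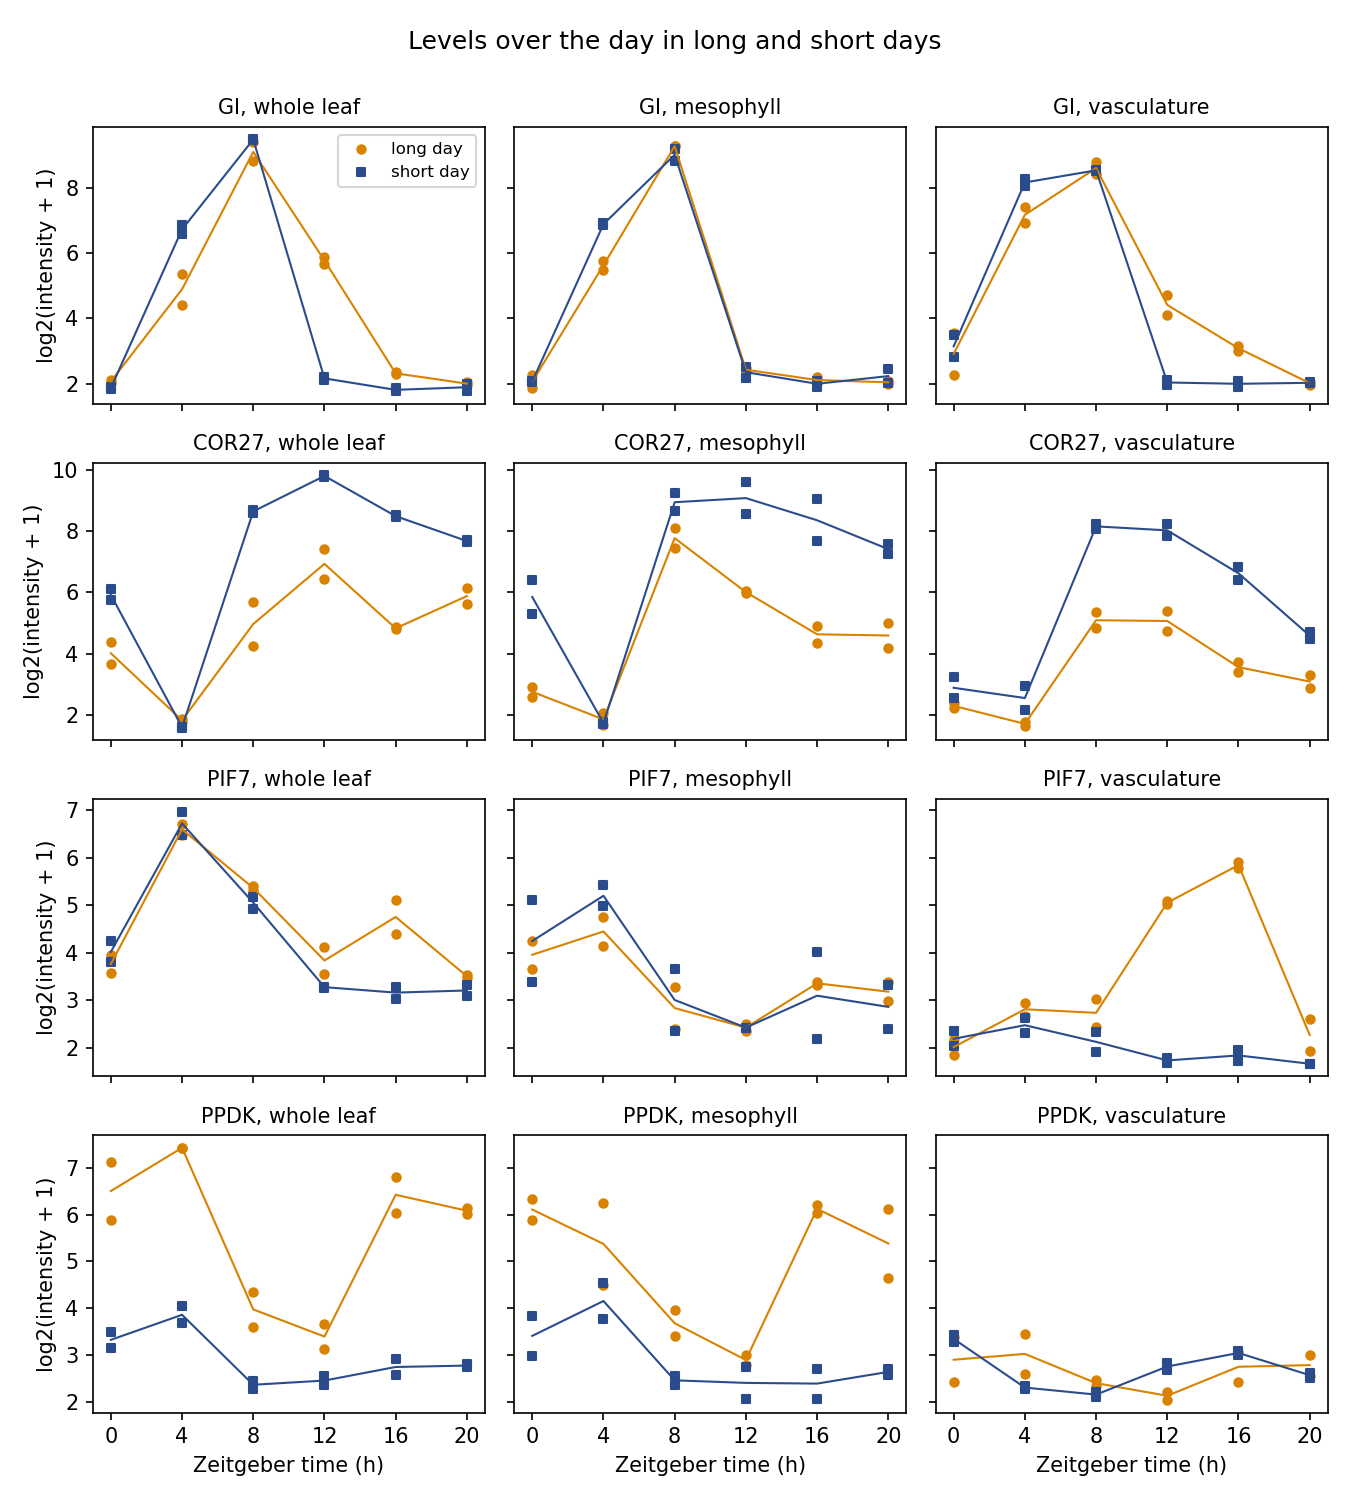
Log2(intensity + 1) (vertical axes) of GI, COR27, PIF7 and PPDK at each Zeitgeber time in hours (horizontal axes) in whole leaf, mesophyll and vasculature; points are single arrays, 1 per day, lines join their means, orange circles are long days and blue squares short days. PIF7 was 1.45 higher on average in long day vasculature than in short day vasculature, and COR27 was lower in long days by 2.29, 2.3 and 2.01 in the 3 tissues.

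By list, cycling members in long day whole leaf, mesophyll and vasculature and then in short day whole leaf, mesophyll and vasculature numbered 3, 5, 3, 8, 6 and 7 of the 9 photosynthesis markers. They numbered 7, 9, 4, 14, 10 and 11 of the 17 nuclear photosynthesis genes, 2, 3, 3, 11, 5 and 7 of the 12 clock-associated genes, and 3, 2, 3, 5, 1 and 6 of the 7 cold genes. Of the 113 ribosomal protein genes 17, 4, 0, 51, 5 and 7 cycled, and of the 15 wound genes 1, 6, 0, 3, 0 and 5. The light-harvesting gene LHB1B2 cycled in all 6 groups, with amplitudes of 2.04, 1.57, 1.16, 0.91, 0.81 and 1.16, and DPE1 of starch breakdown in all 6, with peaks at 11.6, 11.6, 8.76, 10.9, 11.4 and 9.09 h. In total 2079 probe sets cycled in long day whole leaf (9.52% of those tested), 2899 in long day mesophyll (13.3%), 689 in long day vasculature (3.16%), 7584 in short day whole leaf (34.7%), 2609 in short day mesophyll (12%) and 3163 in short day vasculature (14.5%), at an adjusted p under 0.03. Of these 142 cycled in all 6 groups and 9893 in at least 1. Mesophyll and vasculature shared 353 in long days (91.5 if independent) and 1164 in short days (378 if independent), and long and short days shared 1598 in whole leaf (722), 1055 in mesophyll (347) and 365 in vasculature (99.8). Peaks fell most often between 8 and 12 h in long day whole leaf (21.1%) and mesophyll (21.7%), between 0 and 4 h in long day vasculature (27.3%), and between 16 and 20 h in short day whole leaf (2009 of 7584), mesophyll (691 of 2609) and vasculature (24.4%).

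Counts of cycling probe sets depended on the test. A search with several 24-hour shapes gave 528, 1489 and 6 in long day whole leaf, mesophyll and vasculature and 854 and 1471 in short day mesophyll and vasculature, while time as a factor gave 4228, 5555 and 1060 in long days. The long day whole leaf count was 1383 without replicate 1, 1382 without replicate 4 and 1370 without replicate 10. The long day vasculature count was 386 without replicate 1, 438 without replicate 3, 459 without replicate 4, 443 without replicate 5, 444 without replicate 8 and 455 without replicate 11.

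The rhythm difference asked whether amplitude or peak time differed between 2 groups. Between vasculature and mesophyll in long days AT1G55960 had the largest vector difference (5.27; limma adjusted p = 0.00018), with an amplitude of 1.38 in vasculature and 3.98 in mesophyll. AT2G47870 cycled in vasculature in both day lengths (amplitudes 2.88 and 3.71) and had amplitudes of 0.09 and 0.12 in mesophyll (limma adjusted p = 8.2e-07 and 0.0054). IMA2 had 2.75 in long day vasculature and 0.05 in mesophyll (limma adjusted p = 0.00039). AT5G35970 (3.08), AT5G54130 (2.58) and AT4G16146 (2.58) were the others in long days. In short days they were AT1G55960 (3.31), AT4G21215 (2.71), AT5G48540 (2.52), AT1G05330 (2.48) and AT3G21670 (2.37). The 2 probe sets that name CDF5, which may not measure the same transcript, both differed in short days (limma adjusted p = 1.2e-05 and 0.0019). FIO1 also differed in short days (limma adjusted p = 0.014). It cycled in mesophyll (amplitude 0.59) and was not called cycling in vasculature (0.16). RVE6 differed in long days (limma adjusted p = 0.015), where it was called cycling in neither tissue. PIF7 peaked at 13.7 h with an amplitude of 1.76 in long day vasculature, against 1.08 h and 0.78 in long day mesophyll, where it was not called cycling (limma adjusted p = 0.0014), and 4.01 h and 0.37 in short day vasculature (limma adjusted p = 0.011). In mesophyll the log2 means of several of these genes lay near background, at 1.9 and 1.92 for the 2 CDF5 probe sets in short days, 1.81 and 1.82 for AT2G47870 in long and short days, 1.63 for IMA2 in long days and 1.65 for AT1G05330 in short days. In short day vasculature this held for AT5G48540 (1.98) and PIF7 (2.01). Low signal alone keeps amplitudes small at such levels, so these differences show no absence of rhythm there. In total 1559 probe sets differed in long days, of which 121 cycled in both tissues, 143 in vasculature alone by the call, 986 in mesophyll alone and 309 in neither, and 1215 had the larger amplitude in mesophyll. In short days 1339 differed, 124 of them cycling in neither tissue, and 871 had the larger amplitude in mesophyll. Among genes cycling in both tissues the median peak was -0.435 h (353 genes; interquartile range -1.62 to 0.735) in vasculature minus mesophyll in long days and -0.539 h (1164 genes; -1.58 to 0.354) in short days.

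Between day lengths the rhythm of AT4G36850 differed in whole leaf, mesophyll and vasculature (limma adjusted p = 0.033, 0.024 and 0.014). It cycled in long days, with peaks at 1.59, 1.71 and 1.72 h, and was not called cycling in short days in any of the 3 tissues (amplitudes 2.68 ± 0.74, 2.29 ± 0.64 and 2.46 ± 0.65). AKINBETA1, a subunit of the energy-sensing kinase SnRK1, had vector differences of 2.89, 3.01 and 2.66, with fitted short day peaks at 16.5, 16.9 and 16.1 h and long day peaks at 1.57, 2.35 and 3.02 h. It was not called cycling in long day whole leaf, short day mesophyll or long day vasculature. AT4G27450 had 3.8 in whole leaf and 3.3 in vasculature. The other genes were AT1G66100 (2.88), AT3G09440 (2.53) and AT5G48490 (2.5) in whole leaf, Cpn60beta2, a plastid chaperonin (2.51), GSTU20 (2.29), AT5G24155 (2.12) and AT5G14120 (1.99) in mesophyll, and AT2G47870 (3.27), AT3G54390 (2.74) and AT3G24230 (2.46) in vasculature. Of the flowering repressors SNZ differed in whole leaf and vasculature (limma adjusted p = 0.013 and 0.0087) and SMZ in whole leaf (limma adjusted p = 0.029). In total 1446 probe sets differed in whole leaf, 504 in mesophyll and 1144 in vasculature, of which 127, 42 and 299 cycled in neither day length. Genes cycling in both day lengths peaked later in long days, by a median of 1.93 h in whole leaf (1372 of 1598 genes later; interquartile range 0.769 to 3.12), 1.26 h in mesophyll (800 of 1055; 0.0365 to 2.5) and 1.67 h in vasculature (282 of 365; 0.214 to 2.82). These are peaks of a fitted cosine, which a change in the shape of a rhythm can move. GI in whole leaf, for example, had its highest mean at ZT8 in both day lengths, with fitted peaks at 8.37 and 6.57 h. In simulated data 5.92% to 8.86% of the calls of the rhythm difference test were unchanged probe sets when each group kept its own spread. This is above the nominal 5%.

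The 3 counts of rhythm differences between day lengths moved by more than 1.5 times when single arrays were left out. In whole leaf the count was 843 without long day replicate 5, 827 without long day replicate 11, and 722, 939 and 843 without short day replicates 2, 4 and 8. In vasculature it was 729, 495 and 415 without long day replicates 1, 5 and 11, and 347, 740 and 499 without short day replicates 2, 4 and 8. In mesophyll it was 293, 267, 309, 159, 214, 311 and 100 without long day replicates 1, 3, 4, 5, 9, 10 and 11. It was 133, 227, 760, 1042, 174, 276 and 260 without short day mesophyll replicates 2, 4, 5, 7, 8, 9 and 11.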

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

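Chosen only after the result was seen were the splits behind the interaction, the 3 tests of the wound genes, the tests of seedling age, normalization and regrouping of the 2 days, and the tests of smaller amplitudes and of single arrays in long day vasculature.

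Several effects differed between groups by a direct test. The tissue difference depended on day length for 497 probe sets. With the tissue difference shared by both day lengths removed, the real split alone, 1 of 100, gave as many. The highest of the others gave 79, so a chance deal of the arrays is argued against. Rhythms differed between vasculature and mesophyll for 1559 probe sets in long days and 1339 in short days, where the highest of 99 other splits gave 478 and 17. They differed between day lengths for 1446 in whole leaf, 504 in mesophyll and 1144 in vasculature, with 23, 6 and 2 as the highest of the other splits. In each of these 5 the real split alone, 1 of 100, reached its count, so a chance deal of the arrays is argued against. The smallest share these splits can give is 1 of 100. A random deal also breaks up any batch that a group shared, so it cannot tell tissue or day length from such a batch.

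For the remaining comparisons the real split was also the 1 of 100 with as many probe sets. A chance deal is argued against there too, with the same limits. Vasculature against mesophyll gave 5570 and 5474 against a highest other of 3588 and 3152. Mesophyll against whole leaf gave 2452 and 2658 against 28 and 2, and vasculature against whole leaf 4391 and 4570 against 145 and 2760. These deals left the real group difference in the values, so an uneven deal carries part of it into its count. How far this made up the highest counts of the other splits was not tested. Long against short days gave 407, 266 and 322 in whole leaf, mesophyll and vasculature against 257, 71 and 164. Cycling gave 2079, 2899 and 689 in long day whole leaf, mesophyll and vasculature against 4, 1 and 1, and 7584, 2609 and 3163 in short days against 375, 13 and 4.

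Wound and early stress genes were far higher in mesophyll than in the other samples. Expression confined to mesophyll in the intact leaf is argued against, since the list's median was 2.84 and 4.26 above whole leaf, while the photosynthesis markers of the same tissue differed by 0.12 and -0.07. After quantile normalization the higher of the 2 day lengths' list medians was -3.38 and the lower -3.81 in vasculature against mesophyll. GCRMA had already normalized the arrays, so a further normalization of its values cannot decide whether the authors' normalization played a part. A response during the isolation stays open, and these values do not argue against it. Vasculature, which was isolated too, lay above whole leaf by medians of 0.15 and 0.47. The mean of the list was higher in each vasculature array (at least 2.97 and 3.25) than in any whole leaf array (at most 2.84 and 2.49). STZ was 4.39 and 6.21 higher. By the list mean both isolated tissues lay above the organ that contains them. It was 6.4 and 6.98 in mesophyll, 3.21 and 3.61 in vasculature, and 2.55 and 2.28 in whole leaf. A difference between the tissues in how they respond to isolation may play a part as a hypothesis and was not tested.

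In short day mesophyll 1296 probe sets differed between day 10 and day 9 by adjusted p alone (846 higher and 450 lower on day 10). With the minimum difference of 1 as well, 146 did. The counts by adjusted p alone were 0, 2 and 0 in long day whole leaf, mesophyll and vasculature. They were 1 and 30 in short day whole leaf and vasculature. Of 32 ways of swapping days, the real one alone gave as many as 1296, and the highest other gave 13. The group was picked for its count among the 6 groups, and 1 of 32 is the smallest share these swaps can give. Chance is therefore not excluded by them. Without both arrays of ZT16 the count by adjusted p alone was 241, of ZT20 427, of ZT0 589 and of ZT8 722. Vascular tissue carried over on 1 day is argued against by a difference of -0.03 between genes higher and lower in vasculature. Quantile normalization left 1326 probe sets (751 higher and 575 lower on day 10). GCRMA had already normalized the arrays, so a further normalization of its values cannot decide on the authors' normalization. Another strength of the wound response cannot be told apart, as its list had a median of 0.05 with members going both ways, and seedling age stays open, with r = 0.22 across genes against short day whole leaf, 0.26 against short day vasculature and -0.28 to -0.11 against the long day groups. Genes are not independent replicates, and 24 of 113 ribosomal protein genes were lower and 1 higher on day 10.

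Fewer probe sets cycled in long day vasculature, 689, than in the other 5 groups. A larger spread between its arrays is argued against by a ratio of 0.98 to the median of the others. A single array is argued against by a highest count of 585 with any array left out, though fewer arrays also lower a count. Replicates 3 and 6, both of day 9, lay nearer to mesophyll on the first principal component (95.4 and 90.8, against 109 or more in the group's other arrays). Leaving out 1 array cannot show an effect of both. Across genes the group's day 10 minus day 9 difference had r = 0.31 with short day vasculature minus mesophyll, the largest of the 6 groups. Whether tissue purity affected the count was not tested. Smaller amplitudes are consistent with a lower count: the ratio of median amplitudes was 0.56 over genes chosen for cycling in the other groups, which raises theirs, and 0.72 over all genes. Short day vasculature also had low amplitudes (medians of 0.13 against 0.12 over all genes, 0.95 against 0.89 over genes cycling in all 6 groups and 0.24 against 0.18 over the chosen genes) but 3163 cycling probe sets, with a residual SD of 0.148 against 0.175. Amplitude was thus not shown to set the count alone, and the effect of tissue and day length, which the design names, stays open and untested.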

How the results depend on the processing

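The separate-spread fit, the runs without long day whole leaf replicate 7, the setting with no offset and the list medians under other scalings were chosen after seeing the data. The number of arrays and, for dim genes, the signal over background limit every value here. Signs were checked for the genes named by rank and for list members, without the ribosomal protein, reproductive and plastid-encoded lists. No difference of these past its call changed sign under the settings tried. Counts with no minimum difference rose to 15985 and 16031 for vasculature against mesophyll in long and short days, 13190 and 14456 for mesophyll against whole leaf, 13863 and 15537 for vasculature against whole leaf, 8253, 3952 and 6231 for day length in whole leaf, mesophyll and vasculature, and 3362 for the interaction, by the construction of that setting. With fewer arrays, day 9 alone gave 194, 78 and 181 for day length in the 3 tissues and day 10 alone 191 and 162 in whole leaf and mesophyll. Cycling with time as a factor gave 4228, 5555 and 1060 in long day whole leaf, mesophyll and vasculature, the search over several shapes gave 528, 1489 and 6 there and 854 and 1471 in short day mesophyll and vasculature, and the cause was not tested. An amplitude of at least 0.5 left 3601 in short day whole leaf and 1541 in short day vasculature, by construction. Rhythm differences tested over cycling genes alone, and so over fewer genes, numbered 2136 between tissues in short days and 2534, 1626 and 1777 between day lengths in whole leaf, mesophyll and vasculature. In mesophyll they numbered 300 with no filter and 790 with a separate spread for each group, and the cause was not tested. For day length at single times, whole leaf at ZT0 gave 510 without long day whole leaf replicate 7, and mesophyll at ZT0, ZT4 and ZT20 gave 398, 504 and 384 with all 72 arrays in 1 fit, where the cause was not tested. The other settings, apart from leaving out single arrays, left these counts within 1.5 times.

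Leaving out 1 array at a time gave 5491 to 5619 and 5450 to 5496 for vasculature against mesophyll in long and short days, 2427 to 2490 and 2599 to 2715 for mesophyll against whole leaf, and 4336 to 4440 and 4551 to 4584 for vasculature against whole leaf. It gave 388 to 458, 239 to 308 and 280 to 341 for day length in whole leaf, mesophyll and vasculature, and 459 to 537 for the interaction. For cycling it gave 1370 to 2284, 2164 to 2621 and 386 to 585 in long day whole leaf, mesophyll and vasculature, and 6315 to 7324, 1784 to 2519 and 2270 to 3115 in short days. For rhythm differences it gave 1221 to 1653 and 1039 to 1593 between tissues in long and short days, and 722 to 1822, 100 to 1042 and 347 to 1465 between day lengths in whole leaf, mesophyll and vasculature. Without long day whole leaf replicate 7, 3578 whole leaf probe sets differed at any time.

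The time point as a replicate block left 5570 and 5474 probe sets for vasculature against mesophyll and moved mesophyll day length to 258, and with the day as a block the rhythm differences were 1514, 1489, 1287, 500 and 986. Deviations of same-numbered arrays correlated between -0.059 and 0.075 across pairs of groups, which shows no pairing by number. A shared harvest with an effect smaller than the noise of single arrays would not be seen this way. Of the mean differences of named genes and list members, 72 fell short of the call with day 9 alone and 64 with day 10 alone, 14 after quantile normalization and 12 after centring. Centring changed the sign of the all-gene median of mesophyll minus whole leaf, from -0.08 to 0.09 in long days and from -0.09 to 0.07 in short days. Quantile normalization changed that of the photosynthesis markers in long days, from 0.12 to -0.01. Of the list medians 129 moved with centring and 54 with quantile normalization.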

Other observations

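The test of the CDF5 probe sets was chosen only after the result was seen.

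Iron deficiency genes had rhythms that differed between tissues in long days for 3 of 10 members, and for 6 when adjusted over the list alone. IMA1, like IMA2 a small peptide gene of iron uptake, had an amplitude of 2.33 in long day vasculature with a peak at 18.4 h, close to the 18.6 h of IMA2. In the list of cell cycle genes 6 of 8 cycled in short day whole leaf, 3 in short day mesophyll and 3 in short day vasculature, and 0 in each of the 3 long day groups; their rhythms differed between day lengths by the direct test for 3 members in vasculature, 1 in whole leaf and 0 in mesophyll. In long days 6 of 15 wound genes had rhythms that differed between vasculature and mesophyll, and in short days 3.

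QQS, a gene that influences starch content, fell by 1.77 in long days and by 2.16 in short days in mesophyll against whole leaf. ATG8B, an autophagy gene, was 2.15 and 2.05 higher in vasculature than in mesophyll, and the small secreted peptide genes LCR68 (4.02 and 4.22) and LCR69 (2.59 and 2.78) were also higher there. The chaperone factor Fes1A was lower there (-2.01 and -2.6). On day 10 in short day mesophyll, AT4G22470 was 2.82 ± 0.54 higher than on day 9 and AT1G18320 differed by -2.55; these 2 were chosen after their values were seen.

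The 2 probe sets that name CDF5 peaked at different times in short day vasculature, the first at 11.7 ± 0.33 h (amplitude 2.08 ± 0.18) and the second at 23.9 ± 0.42 h (1.64 ± 0.18; SE, n = 12 arrays). That both measure the same transcript is argued against by these peaks, which lay 11.8 ± 0.54 h apart. In short day whole leaf, where both were dim, the peaks were at 11.4 ± 0.69 and 23.8 ± 0.68 h. In long day vasculature the second peaked at 0.88 h and the first was not called cycling. Which transcript each measures was not tested; the RefSeq table places a long noncoding RNA, AT1G69572, over CDF5.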
